A study of Mus musculus with 19 samples.

How the data were processed

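Total RNA from mouse embryonic stem cells (ESC) and epiblast-like cells (EpiLC) was measured on an Illumina bead array. Per the labels, tamoxifen at 1 µM for 36 h induced a knockout of Foxd3, and samples given ethanol (the solvent) stand as the wild-type controls. The 19 arrays hold 12 samples in 4 groups of 3: ESC in ethanol, ESC in tamoxifen, EpiLC in ethanol and EpiLC in tamoxifen. Of the 12 samples, 7 were hybridized in both of 2 hybridization rounds and 5 in a single round. Round 1 holds 11 arrays and round 2 holds 8. The EpiLC ethanol samples were all hybridized in round 1 alone. The ethanol sample of ESC number 1 was hybridized in round 2 alone.

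The deposited raw table gives, per probe and array, the mean bead intensity on a linear scale, without normalization between arrays. The same deposited table gives a detection p-value for each probe against the negative control beads of its array, the standard error over beads and the number of beads. A further deposited table gives intensity values that the authors normalized between arrays, on a linear scale with nearly equal quartiles. The submitters' notes name limma for it without a version or a method. In that table there are 10 values below 0, on 8 arrays, all of round 2, and values under 1 were set to 1 before the logarithm. The raw table was used for the main values and the authors' table as an alternative.

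The 25697 probes were read on all 19 arrays. Between 10330 and 11481 probes per array had a detection p-value under 0.01. Median intensity was 149 to 176 on round 1 arrays and 190 to 220 on round 2 arrays, and the median number of beads per probe was 36 to 39. In ESC, intensity and detection followed the treatment. Round 1 medians were 149 to 154 in ethanol and 166 to 176 in tamoxifen, with 10330 to 10556 and 10750 to 11264 probes detected. Round 2 medians were 192.8 to 205.7 and 205.8 to 219.7, with 10685 to 10842 and 11014 to 11262 probes detected. In EpiLC the round 1 ranges of the treatments overlapped. The comparisons use 1 value per sample, so the 12 samples, not the 19 arrays, limit their precision. The arrays were background-corrected and normalized together with neqc of limma 3.58.1 in R 4.3.3 (normexp with background estimated from the detection p-values, offset 16, quantile normalization, log2). A fit of sample plus hybridization round per probe then gave 1 value per sample. Between the rounds 3362 of 9422 genes differed at an adjusted p under 0.05, with a median absolute log2 shift of 0.14. After group and round were removed, the 2 arrays of a sample correlated at 0.103 to 0.345. The round 1 array of such a sample correlated negatively with the round 2 arrays of the other samples of its group. Removing the mean of a small group by itself makes correlations between its samples negative.

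Probes with a detection p-value under 0.01 on at least 3 of 19 arrays were kept, which left 12529 probes. Probes were named through the platform's gene identifiers: 23978 carried 1 symbol (23962 matched by gene identifier, 9 by accession, 7 kept the platform's name) and 1719 had no entry. For each symbol the probe with the highest mean was used, which gave 9422 features, of which 8680 had a symbol. Of 2231 genes with several kept probes, 0 had probes called in opposite directions for either tamoxifen effect, and 19 did for EpiLC against ESC in ethanol.

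Group means were compared with lmFit and eBayes of limma on the 12 values, in 5 contrasts: tamoxifen against ethanol in ESC and in EpiLC, EpiLC against ESC in ethanol and in tamoxifen, and the difference of the tamoxifen effects (the interaction). A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Errors of log2 changes are the standard errors (SE) of these fits, with n = 3 samples per group. Nothing in the labels says that samples of a group are separate cultures, so the p-values measure the spread between these samples, which may be technical. A comparison of 3 against 3 by exact permutation cannot give a p below 0.1. For a gene detected on no array of the lower group, the change is given as a lower bound: the mean normalized intensity of the higher group over that of the lower group after each array of the latter was raised to the lowest detected signal on that array. A gene detected on some arrays of the lower group keeps its fitted change, but where its mean there lies under the lowest detected signal the size depends on the background. Among the changes given this holds for Fst, Sytl1, Pdzk1, Celf4, Ifit2, Cxcl10, Egln3, Foxp1, Esrp1, Slc40a1, Tcstv1 and Plk1, and for Spic in tamoxifen. No fold is given where a bound is under 1 or where the gene was detected in neither group.

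Whether the sample numbers pair the samples was decided from correlations of the deviations from the group means, not from calls. Deviations of same-numbered ethanol and tamoxifen samples correlated at 0.398, 0.371 and 0.471 in ESC and at 0.547, 0.567 and 0.497 in EpiLC. For same-numbered ESC and EpiLC samples in tamoxifen the values were 0.129, 0.163 and 0.215. These all exceed 0.1, so the numbers were taken to pair the samples in these comparisons. The pairing comes from the data, since the labels do not say what a number marks. The main model has no block, as fixed beforehand, and the model with the number as a block is an alternative.

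Before the data were examined, 23 gene lists, the contrasts, the rule for named genes and most alternatives were fixed. Lists were tested with camera (preset correlation 0.01, adjusted over the 23 lists within a contrast), with an estimated correlation and with fry as alternatives. Camera compares a list with the other genes, while fry asks whether the list itself moves on balance in one direction, so the 2 test different hypotheses. For each list the called members are counted over all genes tested and adjusted over the list alone. Members off the array or removed by the probe filter were not tested. The tested number can lie well below the list size, as with 8 of 18 for neural crest and 5 of 20 for neuroectoderm. Over all members of the 23 lists, tested or not, 26 stand in several lists. The rule named Foxd3, the 6 genes with the largest rise and the 6 with the largest fall in each tamoxifen effect and in EpiLC against ESC in ethanol. These had to be called, not overlap between the groups, have a usual symbol and be detected on every array of the higher group. The rule also named up to 3 called members per list (or, with no call, the member with the smallest p), 5 genes per direction for the interaction and 4 per direction for calls shared by both tamoxifen effects. EpiLC against ESC in tamoxifen takes the genes named in ethanol.

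The tamoxifen effects and the EpiLC against ESC change in ethanol share ethanol samples. Their correlation and covariance across genes are therefore set beside those of 100 simulated draws of noise with a shared control. The draws hold no change with tamoxifen and none between cell types. Alternatives covered background correction, normalization, the authors' table, the probe filter, the treatment of hybridization rounds, probes per gene, the samples in the fit, the sample number as a block, variance moderation, array weights, stricter thresholds and leaving out each sample. Blocking by slide was not run because the files name none.

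The combining of arrays and the fit were tested on simulated normalized values of the genes tested, with 50 changed genes per size and independent samples. Background correction, normalization, the probe filter and the choice of probes were not simulated. At log2 changes of 0.5, 1, 1.5 and 2, the share recovered was 36, 90, 98 and 100% for the ESC effect, 40, 84, 100 and 100% for the EpiLC effect, and 6, 70, 94 and 100% for the interaction. For EpiLC against ESC it was 30, 88, 100 and 100% in ethanol and 32, 98, 100 and 100% in tamoxifen. False calls made up 1.82% of all calls for the ESC effect, 4.14% for the EpiLC effect, 4.07% for EpiLC against ESC in tamoxifen, 7.56% for it in ethanol and 8.78% for the interaction. The last pair exceed the nominal 5%, with 13 false calls each in a single simulated data set per contrast, which is too little to fix the rate. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.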

Results

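Gene expression was measured in mouse embryonic stem cells (ESC) and in epiblast-like cells (EpiLC), the state reached when ESC leave naive pluripotency. Each cell type was given tamoxifen to delete Foxd3, a forkhead transcription factor, or ethanol, the solvent. Each of the 4 groups holds 3 samples, and 7 of the 12 samples were hybridized to 2 arrays, so 19 arrays were read. Between 40.2 and 44.7% of the 25697 probes were detected per array. Over the 12 samples, the principal component that separated ESC from EpiLC carried 82.4% of the variance, and the next, which separated tamoxifen from ethanol, carried 5.35%.

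The deleted gene itself could not be followed. Foxd3 has 1 probe on the array, which was detected on 0 of 19 arrays, with a lowest detection p-value of 0.239. Its log2 change with tamoxifen was -0.06 in ESC (SE 0.09, n = 3 per group) and 0.04 in EpiLC (SE 0.09). The unadjusted p from limma was 0.532 and 0.696. The loss of Foxd3 rests on the labels.

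The comparison of tamoxifen with ethanol in ESC asks which transcripts change when Foxd3 is deleted in naive cells. Gata6, a transcription factor of primitive endoderm, rose 3.82-fold (log2 1.93, SE 0.22, n = 3 per group, adjusted p = 0.000378). Secretin (Sct) rose 3.78-fold (SE 0.20 in log2, adjusted p = 0.000223), and Rgcc, a regulator of the cell cycle, rose 3.77-fold (SE 0.16 in log2). The largest fall among the named genes was that of Lefty1, a secreted inhibitor of Nodal signalling, which fell by 2.14 on the log2 scale (SE 0.13, adjusted p = 3.03e-05), and its relative Lefty2 fell by 1.16 (SE 0.12). Id2, an inhibitor of differentiation factors, was not detected in ethanol and rose at least 1.86-fold. Sytl1, detected on 2 of 5 ethanol arrays, rose by a fitted 1.74 (SE 0.18) and Cpz rose at least 1.51-fold. Further genes with large falls were Slc47a1, a cation exporter (-1.58, SE 0.19), Nfatc4 (-1.48, SE 0.22), the receptor Notch4 (-1.48, SE 0.14), Pnma2 (-1.42, SE 0.25) and Bahcc1 (-1.38, SE 0.09). Normalized intensities of 8 genes are plotted by sample and group.

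**Figure D1:**
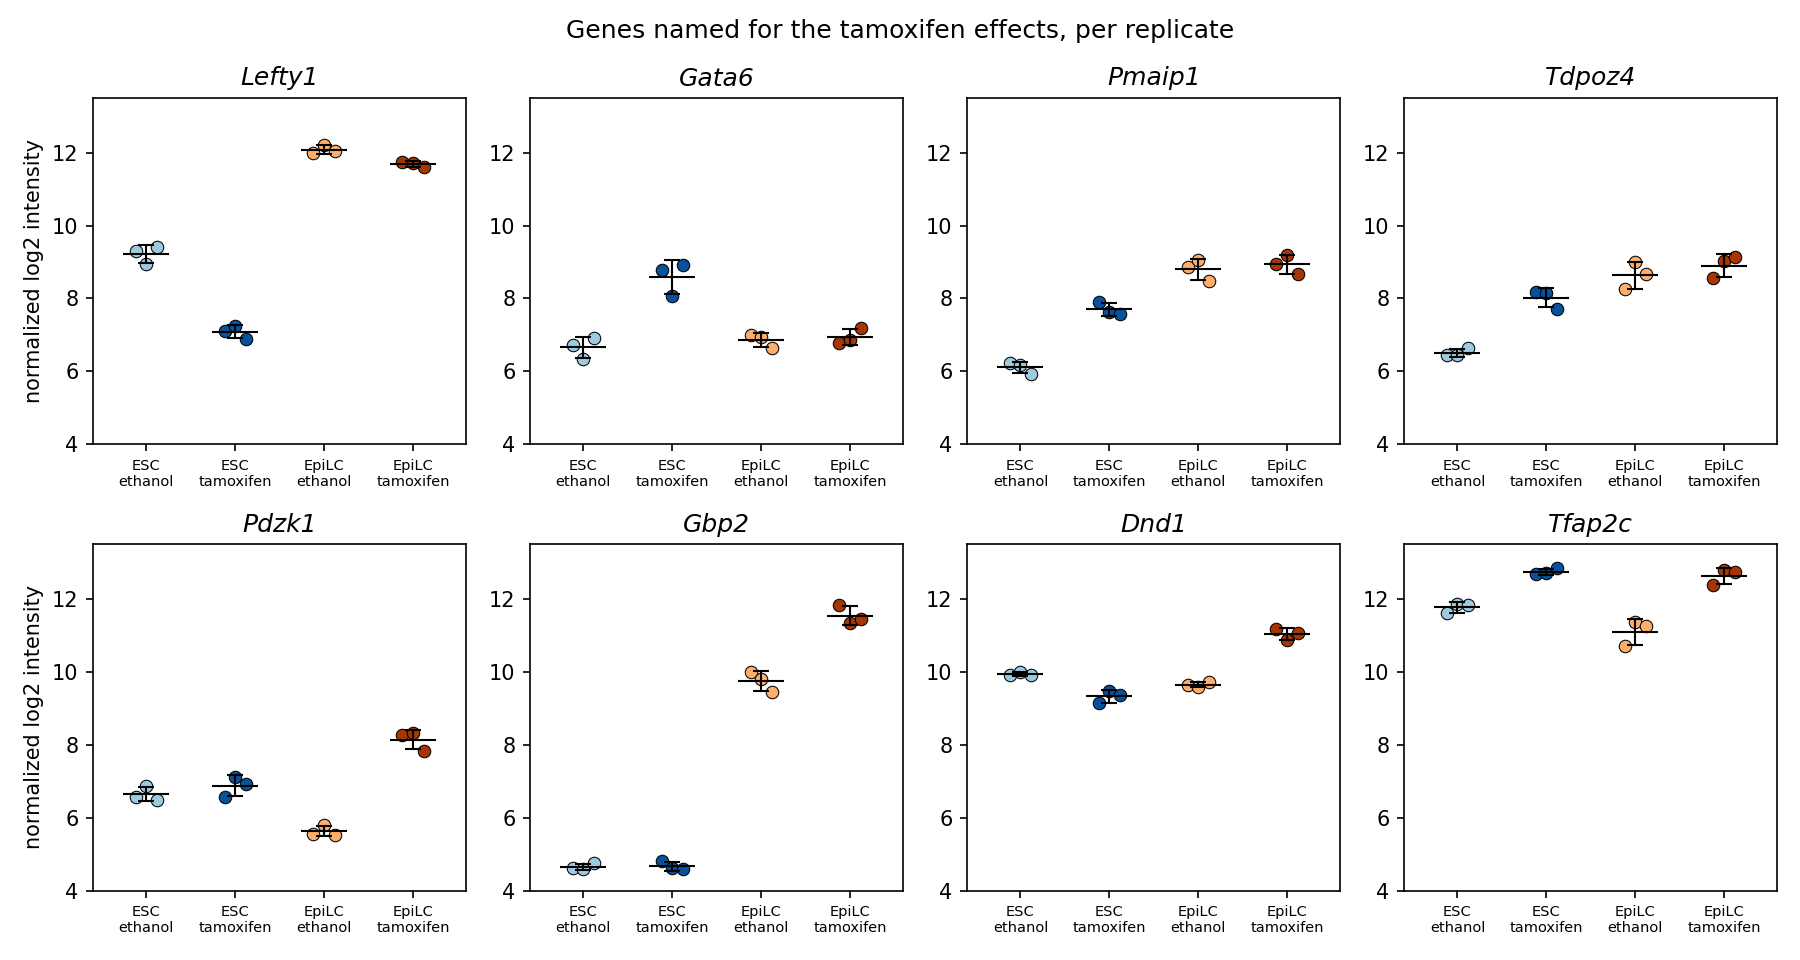
Normalized log2 intensity (vertical axis) of 8 genes in the 4 groups, with 1 point per sample (n = 3) and the mean with its SD. Lefty1 is lower and Gata6, Pmaip1 and Tdpoz4 are higher in ESC given tamoxifen, while Pdzk1, Gbp2, Dnd1 and Tfap2c are higher in EpiLC given tamoxifen. In ESC given tamoxifen, Tfap2c is higher too and Dnd1 is lower.

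Targets of the tumour suppressor p53 rose as a list in ESC, though not all of them did. Of 18 tested, 8 rose and 0 fell over all genes tested, and 10 rose and 1 fell adjusted over the list alone (camera adjusted p = 3.23e-07, and 0.0112 with an estimated correlation). Pmaip1, a pro-apoptotic factor, rose by 1.59 (SE 0.17), the kinase Plk2 by 1.24 (SE 0.18), and the death receptor Fas, not detected in ethanol, rose at least 1.71-fold. Cdkn1a, a further member, was not called. Its normalized log2 intensities overlapped, at 12.03, 12.25 and 12.20 in ethanol and 11.98, 12.35 and 12.48 in tamoxifen.

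Genes of the two-cell-like state, a rare state of cultured ESC that resembles the cleavage embryo, rose as well. Of 10 tested, 6 rose and 0 fell, and 8 rose adjusted over the list alone (camera adjusted p = 2.65e-07). With an estimated correlation the list had an adjusted p = 0.125. Tdpoz4 rose by 1.51 (SE 0.20), Tmem92 by 1.14 (SE 0.15) and Arg2 by 1.13 (SE 0.17). Of 15 sterol biosynthesis genes tested, 2 fell and 0 rose, and 3 fell adjusted over the list alone (camera adjusted p = 0.0460, and adjusted p = 0.507 with an estimated correlation). Cyp51, a demethylase of the pathway, fell by 0.43 (SE 0.08), a call lost on scaling to equal medians (adjusted p = 0.0820) and on round 1 arrays (0.283). The sterol call was lost on scaling to equal medians (adjusted p = 0.102), on the arrays of round 1 (0.202) and with fry (0.0525). It was also lost without ethanol sample 2 (0.0518) or 3 (0.0831) and without tamoxifen sample 1 (0.0513), 2 (0.0643) or 3 (0.0632).

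The lists of pluripotency genes were not called in ESC. Of 16 naive pluripotency genes tested, 2 rose and 2 fell (4 and 3 adjusted over the list alone, camera adjusted p = 0.923), among them falls of Tcl1 by 0.90 (SE 0.17) and of Gbx2 by 0.75 (SE 0.13). Of 16 formative and primed epiblast genes, 3 rose and 3 fell (3 and 3 over the list alone, adjusted p = 0.534), with Tcf15 lower by -1.14 (SE 0.15). Of 16 shared pluripotency genes, 0 rose and 1 fell (0 and 1 over the list alone, adjusted p = 0.225). That 1 gene, Pou5f1, had a log2 change of -0.31 (SE 0.08, adjusted p = 0.0300), and its call was lost when any 1 of the 6 ESC samples was left out. The adjusted p was then 0.0766, 0.0893 and 0.0833 without ethanol sample 1, 2 or 3, and 0.0639, 0.109 and 0.0602 without tamoxifen sample 1, 2 or 3. Of 12 germline genes, 3 rose and 1 fell (5 and 1 over the list alone, adjusted p = 0.0899, and 0.0304 with the sample number as a block, with a range of 0.0304 to 0.507 over 12 alternatives). Nanos3, an RNA-binding protein of germ cells, rose by 1.25 (SE 0.22), and Tfap2c, a factor shared by germ cells and trophoblast, rose by 0.98 (SE 0.17).

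Lineage markers in ESC gave single changes and no list call. Of 12 primitive endoderm genes tested, 2 rose and 1 fell (3 and 2 over the list alone, camera adjusted p = 0.322): Gata6, Dab2, which rose by 1.39 (SE 0.17), and Fst, which fell by 0.76 (SE 0.15). Of 17 trophoblast genes, 4 rose and 0 fell (6 and 2 over the list alone, adjusted p = 0.113), with Gata2 higher by 0.92 (SE 0.17). For mesoderm and definitive endoderm 0 of 11 genes were called (0 over the list alone, adjusted p = 0.852), and the gene with the smallest p, Cdx1, had a log2 change of -0.63 (adjusted p = 0.0974). For neural crest 0 of 8 were called (0 over the list alone, adjusted p = 0.923), and Twist1 had -0.36 (adjusted p = 0.0652). With the sample number as a block, Cdx1 and Twist1 were called. For neuroectoderm 1 of 5 fell (1 over the list alone, adjusted p = 0.322), which was Gbx2. For fibroblast and stroma, 1 of 9 rose and 1 fell (1 and 1 over the list alone, adjusted p = 0.923), and Vim fell by 0.62 (SE 0.12).

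Signalling and stress lists in ESC gave no camera call either. Of 15 FGF-ERK response genes, 2 rose and 1 fell (3 and 3 over the list alone, camera adjusted p = 0.993), with cyclin D1 (Ccnd1) lower by -0.65 (SE 0.07). Of 10 Nodal and TGF-beta response genes, 1 rose and 2 fell (1 and 2 over the list alone, adjusted p = 0.342, and 0.0238 with fry): Id2, Lefty1 and Lefty2. Of 10 Wnt response genes, 0 rose and 1 fell (0 and 1 over the list alone, adjusted p = 0.342). Of 13 interferon response genes, 1 rose and 0 fell (1 and 0 over the list alone, adjusted p = 0.923). Of 18 hypoxia and glycolysis genes, 2 rose and 2 fell (2 and 3 over the list alone, adjusted p = 0.378), and Ddit4 rose by 0.97 (SE 0.15). Of 18 genes of the unfolded protein and amino acid stress list, 1 rose and 3 fell (1 and 5 over the list alone, adjusted p = 0.175). The cell cycle list had 0 of 14 called (0 over the list alone, adjusted p = 0.397), and Birc5 had a log2 change of -0.17 (adjusted p = 0.207). Of 19 histone acetylation and Brg1 complex genes, 0 rose and 1 fell (0 and 2 over the list alone, adjusted p = 0.397). Of 12 forkhead family genes, 0 were called (0 over the list alone, adjusted p = 0.835), and Foxa3 had -0.68 (adjusted p = 0.0590), which was called with the block. The median, mean and test of a list differed in sign for mesoderm and definitive endoderm, FGF-ERK response, fibroblast and stroma, neural crest and forkhead family.

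Over all genes in ESC, 526 rose and 330 fell of 9422 tested, and 2215 had an unadjusted p under 0.05. At least a 2-fold change was reached by 111 of the genes that rose and 24 of those that fell. The tamoxifen and ethanol samples did not overlap for 3064 genes (32.5%), among them all 856 called. Chance gives 10% for independent samples, but same-numbered samples correlate, so 10% is not the exact chance share here. Before normalization, ESC tamoxifen arrays were brighter than ESC ethanol arrays in each round. Whether this bears on the balance of 526 and 330 was not tested. Scaling to equal medians in place of equal quantiles gave 794 genes higher and 120 lower. The median log2 change of all genes under that scaling was 0.09 in ESC, -0.09 in EpiLC, -0.10 for EpiLC against ESC in tamoxifen and -0.18 for the difference of the tamoxifen effects. The count of 856 was 2039 with the sample number as a block, 390 on round 1 arrays, 690 on round 2 arrays, 1448 with array weights and 300 without number 1 in both groups. It was 523 without ethanol sample 1, 525 without ethanol sample 3, 523 without tamoxifen sample 1 and 537 without tamoxifen sample 3.

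The same comparison in EpiLC asks which transcripts differ in these cells after the 36 h of tamoxifen meant to delete Foxd3. Pdzk1, a scaffold protein of membrane transporters, rose 5.70-fold (log2 2.51, SE 0.17, n = 3 per group, adjusted p = 8.02e-05), a fitted size, since it was detected on 1 of 3 ethanol arrays. Foxd4, a close relative of Foxd3, rose 4.44-fold (SE 0.22 in log2), and the interferon-inducible GTPases Gbp2b and Gbp2 rose 4.07-fold (SE 0.25 in log2) and 3.47-fold (SE 0.15 in log2). Sfn, a 14-3-3 protein of epithelia, rose by 1.77 (SE 0.18) and Slc5a5, the sodium-iodide symporter, by 1.77 (SE 0.13, adjusted p = 8.02e-05). Eras, a Ras protein of ESC, fell by 1.67 (SE 0.27), and the transcription factor Etv1 fell by 1.19 (SE 0.17). Avpr1a, a vasopressin receptor, was at least 1.83-fold lower and Ldb2 at least 1.30-fold lower. Celf4 fell by 1.16 (SE 0.21) and the carbonic anhydrase Car14 fell by 1.13 (SE 0.10, adjusted p = 0.000236).

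Trophoblast genes gave the smallest list p in EpiLC with camera at the preset correlation. Of 17 tested, 10 rose and 0 fell, and 13 rose adjusted over the list alone (camera adjusted p = 9.40e-10, and 0.0318 with an estimated correlation). Tfap2c rose by 1.53 (SE 0.17, adjusted p = 0.000592), Gata3 by 1.30 (SE 0.21) and Ascl2 by 1.02 (SE 0.16), all transcription factors of the early placenta. The tested neural crest genes rose as a list too: 4 of 8 rose and 0 fell, and 6 rose adjusted over the list alone (adjusted p = 1.61e-04, and 0.0318 with an estimated correlation). The list holds 18 genes, of which 14 are on the array, so most of it was not tested. Twist1, a tested member that was not called, lay lower in tamoxifen (7.67 to 7.78) than in ethanol (7.82 to 8.14). The peptide Edn1 rose by 1.32 (SE 0.21) and the homeobox factor Msx2 by 0.84 (SE 0.14). Msx1 rose by 1.09 (SE 0.22), a call lost without tamoxifen sample 3 (adjusted p = 0.0529, with a range of 0.000499 to 0.0601 over the alternatives).

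Naive pluripotency genes also rose in EpiLC, with 4 of 16 called higher and 0 lower, and 6 higher adjusted over the list alone (camera adjusted p = 0.00337, and adjusted p = 0.239 with an estimated correlation). Tbx3 rose by 1.15 (SE 0.14) and Klf5 by 0.62 (SE 0.10), both transcription factors of naive cells. Esrrb had a log2 change of 0.55 (SE 0.17, adjusted p = 0.0722). A set of 132 other genes enriched in ESC had a median log2 change of 0.276 (SD 0.362), and 23 of them were called higher and 2 lower. These were called lower in EpiLC than in ESC in ethanol by at least 2 on the log2 scale. They were also detected on every EpiLC array, so they are part of the ESC-enriched genes. The EpiLC ethanol samples enter both their choice and their change, which can favour a rise. Of 12 germline genes, 3 rose and 0 fell, and 4 rose adjusted over the list alone (adjusted p = 0.00757, and adjusted p = 0.239 with an estimated correlation). Dnd1, an RNA-binding protein of germ cells, rose by 1.39 (SE 0.11, adjusted p = 0.000115), and Nanos3, not detected in ethanol, rose at least 1.69-fold. The germline call was lost without ethanol sample 3 (adjusted p = 0.0727, with a range of 0.000426 to 0.239 over 11 alternatives).

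Interferon response genes rose in EpiLC, with 6 of 13 called higher and 1 lower, and 7 and 1 adjusted over the list alone (camera adjusted p = 0.00337, and adjusted p = 0.226 with an estimated correlation). The chemokine Cxcl10, detected on 1 of 3 ethanol arrays, rose by a fitted 1.61 (SE 0.27) and the ubiquitin-like modifier Isg15 by 1.05 (SE 0.18). The 1 member called lower, Ifit2, had -0.83 (SE 0.18), a call lost without ethanol sample 2 (adjusted p = 0.0521) or tamoxifen sample 2 (0.0596) or 3 (0.0749). Of 10 two-cell-like genes, 3 rose and 0 fell, and 3 rose over the list alone (adjusted p = 0.00174, and adjusted p = 0.239 with an estimated correlation), with Tcstv1 higher by 0.91 (SE 0.15) and Tmem92 by 0.75 (SE 0.15). Of 18 p53 targets, 2 rose and 0 fell, and 3 rose over the list alone (adjusted p = 0.00174, and 0.0439 with an estimated correlation). Fas rose at least 1.49-fold and Mdm2 rose by 0.50 (SE 0.09). Of 15 sterol biosynthesis genes, 3 fell and 0 rose, and 4 fell over the list alone (adjusted p = 0.00757, and adjusted p = 0.239 with an estimated correlation). Insig1, which retains the sterol sensor in the endoplasmic reticulum, had a log2 change of -0.42 (SE 0.09), a call lost without ethanol sample 1 (adjusted p = 0.0517) or tamoxifen sample 1 (0.0603). The sterol list's call was lost without ethanol sample 1 (adjusted p = 0.0715, with a range of 0.000515 to 0.239 over 11 alternatives).

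**Figure D2:**
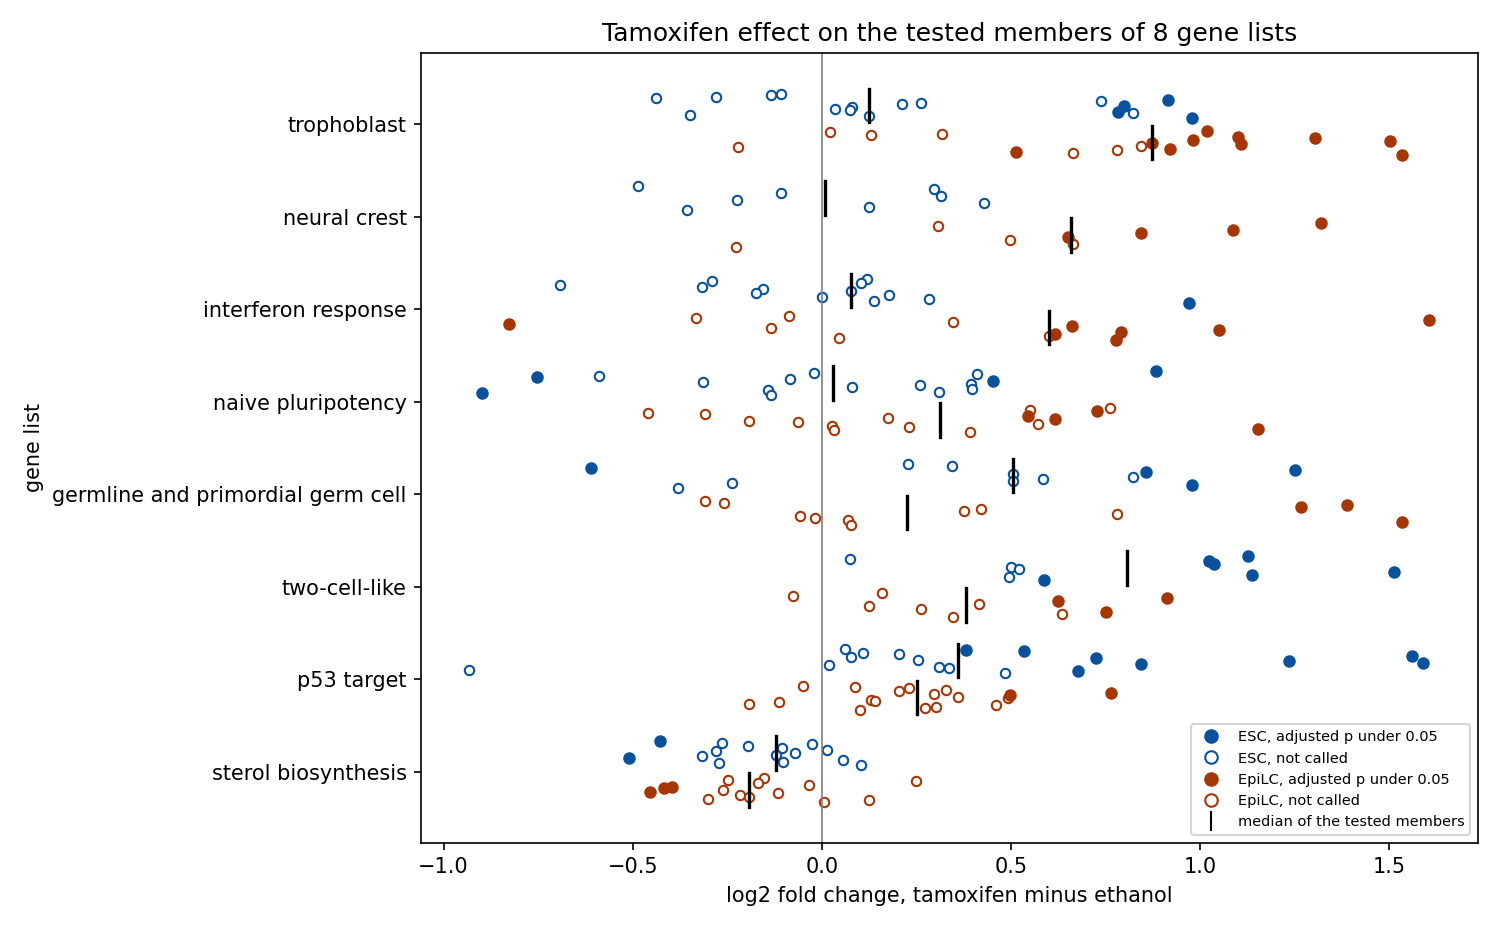
Log2 change with tamoxifen (axis in log2 units) of the tested members of 8 gene lists in ESC (blue) and EpiLC (brown), with filled points for an adjusted p under 0.05 and a bar at the median. Members not detected in a group stand at their fitted values. Among trophoblast genes 4 of 17 are called higher in ESC and 10 of 17 in EpiLC, and among p53 targets 8 of 18 in ESC and 2 of 18 in EpiLC.

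The other lists were not called in EpiLC. Of 16 formative and primed epiblast genes, 2 rose and 3 fell (2 and 5 over the list alone, camera adjusted p = 0.454): Car4 rose by 1.24 (SE 0.14) and the kinase Pim2 fell by 0.84 (SE 0.11). Of 15 imprinted genes, 2 rose and 0 fell (3 and 1 over the list alone, adjusted p = 0.0627). The growth factor Igf2 rose by 0.99 (SE 0.12). The imprinted list had an adjusted p = 0.0470 with the block, 0.0290 with fry and 0.0256 without tamoxifen sample 1, in a range of 0.0256 to 0.314 over 11 alternatives. In ESC 1 of 15 rose and 0 fell (2 and 0 over the list alone, adjusted p = 0.108), with 0.0354 without ESC tamoxifen sample 3 and up to 0.507 over 12 alternatives. For mesoderm and definitive endoderm 0 of 11 EpiLC genes were called (0 over the list alone, adjusted p = 0.144, 0.0470 with the block, 0.0432 without tamoxifen sample 2, up to 0.408 over 11 alternatives), and Gsc had a log2 change of 0.82 (adjusted p = 0.0999). For primitive endoderm 1 of 12 rose and 0 fell (1 and 0 over the list alone, adjusted p = 0.239, 0.0273 without tamoxifen sample 2, up to 0.661 over 11 alternatives). For shared pluripotency 0 of 16 were called (0 over the list alone, adjusted p = 0.729), and Sall4 had 0.26 (adjusted p = 0.0524). For neuroectoderm 0 of 5 were called (0 over the list alone, adjusted p = 0.689), and Gbx2 had -0.31 (adjusted p = 0.181). With the block, Gsc, Sall4 and Gbx2 were called.

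The signalling and stress lists were likewise without a camera call in EpiLC. Of 15 FGF-ERK response genes, 3 rose and 2 fell (3 and 2 over the list alone, camera adjusted p = 0.689). Of 10 Wnt response genes, 1 rose and 0 fell (1 and 1 over the list alone, adjusted p = 0.689). Of 10 Nodal and TGF-beta response genes, 0 were called (0 over the list alone, adjusted p = 0.708), and Lefty1 had a log2 change of -0.40 (adjusted p = 0.0963). Of 9 fibroblast and stroma genes, 1 rose and 0 fell (3 and 1 over the list alone, adjusted p = 0.256, and 0.0358 with fry), and S100a6 rose by 1.16 (SE 0.17). Of 18 hypoxia and glycolysis genes, 1 rose and 0 fell (3 and 0 over the list alone, adjusted p = 0.781), which was Ddit4 at 0.97 (SE 0.15). Of 18 genes of unfolded protein and amino acid stress, 2 rose and 0 fell (2 and 0 over the list alone, adjusted p = 0.809). For the cell cycle 0 of 14 were called (0 over the list alone, adjusted p = 0.392, and 0.0273 with fry), and Plk1 had -0.55 (adjusted p = 0.0746, and 0.0243 without ethanol sample 2). For histone acetylation and the Brg1 complex 0 of 19 were called (0 over the list alone, adjusted p = 0.849), and Hdac4 had 0.30 (adjusted p = 0.149). Of 12 forkhead genes, 1 rose, Foxd4, and 0 fell (1 and 0 over the list alone, adjusted p = 0.897). The median, mean and test differed in sign for shared pluripotency, hypoxia and glycolysis, unfolded protein and amino acid stress, and forkhead family.

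Over all genes in EpiLC, 447 rose and 204 fell, and 2117 had an unadjusted p under 0.05. At least a 2-fold change was reached by 76 of the genes that rose and 9 of those that fell. The tamoxifen and ethanol samples did not overlap for 2328 genes (24.7%, where chance gives 10% for independent samples, which these are not), among them 650 of the 651 called. The count of 651 was 1876 with the sample number as a block, 336 on round 1 arrays, which hold all 6 samples, 212 in a fit of the 2 groups alone, 275 without number 1 in both groups, 1064 with the authors' normalized values, and 315 higher with 243 lower under scaling to equal medians. It was 411 without ethanol sample 1, 425 without tamoxifen sample 2 and 357 without tamoxifen sample 3.

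Whether the loss of Foxd3 acts alike in both cell types was asked from shared calls and from the difference of the effects. Of 9422 genes, 132 rose in both cell types where 25.0 would be shared by independent calls (two-sided Fisher exact p = 3.97e-63), and 36 fell in both where 7.14 would be (p = 4.39e-16). All groups share a single estimate of the spread per gene, so a gene with a small estimate is called more readily in both cell types. The counts for independent calls and the Fisher p-values do not allow for this. Sct rose by 1.92 in ESC and 1.48 in EpiLC (SE 0.20 each), Sfn by 1.43 and 1.77 (SE 0.18 each), and the acyltransferase Gpat3 rose 2.82-fold and 2.68-fold (SE 0.23 each in log2). Cstdc1 rose by 1.47 (SE 0.21) in ESC and at least 1.23-fold in EpiLC. Among genes that fell in both, Qprt, an enzyme of NAD synthesis, fell by 1.05 and 0.89 (SE 0.13 each) and Notch4 by 1.48 and 0.82 (SE 0.14 each). The Wnt antagonist Sfrp1 fell by 0.93 and 0.75 (SE 0.16 each), and its EpiLC call was lost without ethanol sample 2 (adjusted p = 0.0517) or 3 (0.0662) or tamoxifen sample 1 (0.0640) or 3 (0.0576). Ppargc1b was at least 1.11-fold lower in ESC and fell by 0.88 (SE 0.21) in EpiLC. Its ESC call was lost without ethanol sample 1 (0.138) or 2 (0.115) or tamoxifen sample 1 (0.0916) or 3 (0.132), and its EpiLC call without ethanol sample 1 (0.0909) or 2 (0.0818) or tamoxifen sample 1 (0.0869) or 3 (0.112).

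Opposite calls were rare: 4 genes rose in ESC and fell in EpiLC where 11.4 would be expected (Fisher exact p = 0.0194), and 8 fell in ESC and rose in EpiLC where 15.7 would be (Fisher exact p = 0.0466). Across genes, which are not independent replicates, the effects correlated at r = 0.318 (rho = 0.265), and 77.2% of the 1327 genes called in either cell type had the same sign. The 168 shared calls became 583 with the sample number as a block, 63 on round 1 arrays and 267 with the authors' normalized values. They became 107 without EpiLC ethanol sample 1, 106 without EpiLC tamoxifen sample 3, 111 without ESC ethanol sample 2, 104 without ESC ethanol sample 3 and 107 without ESC tamoxifen sample 3.

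**Figure D3:**
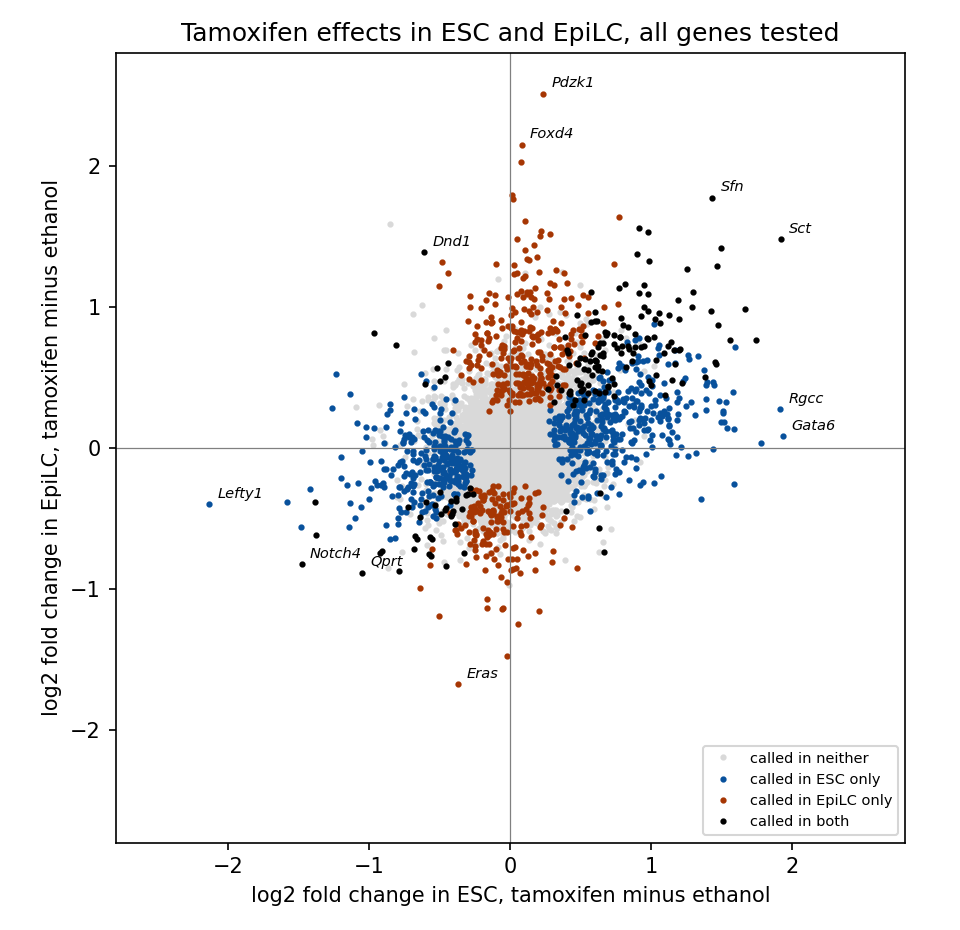
Log2 change with tamoxifen in ESC (horizontal axis) and in EpiLC (vertical axis) for 9422 genes, coloured by the cell type in which a gene is called. The correlation across genes is 0.318, and genes called in both cell types mostly lie in the quadrants of equal sign, 132 higher in both and 36 lower in both.

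The test of the difference between the effects found 133 genes with a more positive and 111 with a more negative effect in EpiLC than in ESC, and 1593 genes had an unadjusted p under 0.05. Dnd1 moved in opposite directions: it fell by 0.61 (SE 0.11, adjusted p = 0.00474) in ESC and rose by 1.39 in EpiLC, a difference of 2.00 (SE 0.15, adjusted p = 0.000284). Pdzk1 had a difference of 2.28 (SE 0.24, adjusted p = 0.00173), with a log2 change of 0.23 in ESC. Edn1 had a difference of 1.80 (SE 0.30). Foxd4 (difference 2.07, SE 0.31) and Gbp2b (1.95, SE 0.35) were detected on no ESC array, so their difference carries the EpiLC effect. In the other direction, Gata6 had a difference of -1.85 (SE 0.31, adjusted p = 0.0124), with a log2 change of 0.08 in EpiLC. Fgfbp3, a binding protein of fibroblast growth factors, had -1.84 (SE 0.22), from 1.58 in ESC and -0.26 in EpiLC. Rgcc had -1.64 (SE 0.23). Id2 (-1.74, SE 0.28) and the elongation factor Eef1a2 (-1.71, SE 0.27) were not detected in ESC ethanol samples, so these 2 are fitted values that depend on the background. On round 1 arrays the adjusted p of the difference was 0.0525 for Gata6, the highest of its alternatives, and 0.0737 for Gbp2b, likewise.

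As groups, the more positive effects in EpiLC were those of trophoblast genes (camera adjusted p = 6.33e-04, 2 of 17 called, 3 adjusted over the list alone, and adjusted p = 0.206 with an estimated correlation) and neural crest genes (0.00120, 2 of 8 called, 4 adjusted over the list alone, and adjusted p = 0.0890 with an estimated correlation). Naive pluripotency genes (0.0196, 2 of 16 called, 4 adjusted over the list alone) and interferon response genes (0.0266, 2 of 13 called, 5 adjusted over the list alone) were also more positive, each with an adjusted p = 0.389 with an estimated correlation. More negative in EpiLC were p53 targets (0.0196, 2 of 18 called, 5 lower and 1 higher adjusted over the list alone, and adjusted p = 0.206 with an estimated correlation) and two-cell-like genes (0.0196, 1 of 10 called, 2 adjusted over the list alone, and adjusted p = 0.389 with an estimated correlation). Examples are Edn1 among neural crest genes, Klf5 (0.93, SE 0.14) among naive genes and Pmaip1 (-1.46, SE 0.24, lost on round 1 arrays with an adjusted p of 0.0538) among p53 targets. The median, mean and test differed in sign for imprinted, germline, cell cycle and sterol genes, none of which was called.

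Several of these group differences rest on few samples. With fry, which asks if a list moves at all and not if it moves more than other genes, the adjusted p was 0.0956 for the naive, 0.0838 for the interferon and 0.0956 for the two-cell-like difference. The naive difference was lost without EpiLC ethanol sample 1 (adjusted p = 0.0942) or 3 (0.0516) or EpiLC tamoxifen sample 2 (0.0860). The interferon difference was lost on round 1 arrays (0.198) and without EpiLC ethanol sample 3 (0.0516), EpiLC tamoxifen sample 1 (0.0802), ESC ethanol sample 1 (0.0853) or ESC tamoxifen sample 3 (0.0957). The p53 difference was lost with the block (0.0524), on round 1 arrays (0.119) and without EpiLC tamoxifen sample 1 (0.0915). The two-cell-like difference was lost on scaling to equal medians (0.0900) and without EpiLC ethanol sample 2 (0.0885), EpiLC tamoxifen sample 1 (0.0802), ESC ethanol sample 3 (0.0554) or ESC tamoxifen sample 1 (0.0501). The unfolded protein and amino acid stress list, at 0.102, was called with the block (0.0376) and without EpiLC ethanol sample 2 (0.0154), EpiLC tamoxifen sample 3 (0.0441), ESC ethanol sample 3 (0.0185) or ESC tamoxifen sample 2 (0.0391). The Wnt response list, at 0.206, was called under scaling to equal medians (0.00633, up to 0.505 over 17 alternatives). The count of 244 genes was 1147 with the block, 61 on round 1 arrays, 397 with the authors' normalized values, and 78 higher with 258 lower under scaling to equal medians. It was 123 without EpiLC tamoxifen sample 3, 134, 159 and 109 without ESC ethanol sample 1, 2 or 3, and 119, 153 and 150 without ESC tamoxifen sample 1, 2 or 3.

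EpiLC were compared with ESC in ethanol to describe the developmental change against which the loss of Foxd3 is read. The growth factor Fgf5, a marker of formative cells, was at least 45.2-fold higher in EpiLC, and Fgf8 at least 22.9-fold higher, neither being detected in ESC (n = 3 per group). Car4 was at least 30.3-fold and Tmem54 at least 18.7-fold higher. Esrp1, a splicing regulator of epithelia, rose by 6.14 on the log2 scale (SE 0.26), and the iron exporter Slc40a1 rose by 5.20 (SE 0.20). These 2 are fitted sizes that depend on the background, with detection on 1 and 2 of 5 ESC arrays. The homeobox gene Crxos fell by 5.88 (SE 0.19) and the transcription factor Spic by 5.14 (SE 0.29). Tcl1, a co-activator of Akt kinase, was at least 30.6-fold lower, Mras at least 28.6-fold, Cabs1 at least 27.5-fold and Pglyrp1 at least 26.2-fold lower.

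Between EpiLC and ESC in ethanol, 56.3% of all 9422 genes tested were called, which is the share to set beside list counts. The list counts that follow were the same adjusted over the list alone unless given. Of 16 naive pluripotency genes, 15 fell and 0 rose (camera adjusted p = 2.45e-08, and adjusted p = 0.0635 with an estimated correlation), with Esrrb lower by -3.99 (SE 0.17) and Tbx3 by -3.96 (SE 0.14). Of 16 formative and primed epiblast genes, 15 rose and 0 fell (6.68e-10, and 0.0425 with an estimated correlation), with the transcription factor Pou3f1 higher by 4.99 (SE 0.12). Imprinted genes rose in 13 of 15 cases, with 0 lower (4.55e-06, and adjusted p = 0.0635 with an estimated correlation): the cell cycle inhibitor Cdkn1c by 3.91 (SE 0.09), Phlda2 by 2.77 (SE 0.19) and Igf2 by 2.75 (SE 0.12). Of 10 two-cell-like genes 9 rose and 0 fell (4.95e-04, and adjusted p = 0.176 with an estimated correlation), with Tcstv1 higher by 2.71 (SE 0.15) and Tdpoz4 by 2.13 (SE 0.20). Of 12 forkhead genes 10 rose and 0 fell (0.00156, and adjusted p = 0.173 with an estimated correlation), with Foxp1, detected on 1 of 5 ESC arrays, higher by a fitted 2.06 (SE 0.31) and Foxn3 by 1.65 (SE 0.11).

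Of 15 FGF-ERK response genes, 11 rose and 1 fell (camera adjusted p = 0.00650, and adjusted p = 0.176 with an estimated correlation). The phosphatases Dusp4 and Dusp6 rose by 4.32 (SE 0.27) and 4.20 (SE 0.26), and Egr1 was at least 12.7-fold higher. The labels state that the ESC medium, not the EpiLC medium, held inhibitors of MEK and GSK and the cytokine LIF. Of 10 Nodal and TGF-beta response genes, 7 rose and 2 fell, and 8 and 2 adjusted over the list alone (0.0157, and adjusted p = 0.176 with an estimated correlation), with Id1 higher by 3.90 (SE 0.16) and Lefty1 by 2.86 (SE 0.13). Of 13 interferon response genes, 8 rose and 3 fell, and 9 and 3 adjusted over the list alone (0.0332, lost with the block at 0.0575, and adjusted p = 0.252 with an estimated correlation), with Bst2 higher by 3.17 (SE 0.16) and Oasl2 at least 2.92-fold higher. The fibroblast and stroma list, with 2 of 9 higher and 6 lower, had an adjusted p = 0.0603. That list was called without EpiLC ethanol sample 3 (0.0341), without ESC ethanol sample 1 (0.0446), on scaling to equal medians (0.0323) and on round 1 arrays (0.0358), and the sterol list, at 0.0786, without EpiLC ethanol sample 2 (0.0363). The other 13 lists were not called. With fry, lists uncalled by camera passed as well: fibroblast and stroma (3.37e-06), neuroectoderm (7.82e-06), hypoxia and glycolysis (1.78e-05), sterol (2.76e-04), trophoblast (0.00116), p53 targets (0.00116), primitive endoderm (0.00153), shared pluripotency (0.00292) and histone acetylation (0.0419). For shared pluripotency and Wnt response genes, and in tamoxifen for mesoderm and definitive endoderm genes and p53 targets, all uncalled, the median, mean and test differed in sign.

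In tamoxifen, 2770 genes were higher and 2556 lower in EpiLC than in ESC (together 56.5% of those tested), and 5753 had an unadjusted p under 0.05. Scaling to equal medians gave 2096 higher and 3007 lower. In ethanol, 2811 were higher and 2489 lower, and 5756 had an unadjusted p under 0.05. Groups did not overlap for 5852 genes (62.1%) in ethanol and 6003 (63.7%) in tamoxifen, where chance gives 10% for independent samples. Fgf5 was at least 67.9-fold and Car4 at least 84.0-fold higher in tamoxifen, and Esrp1 rose by 5.93 (SE 0.26). Crxos fell by 5.82 (SE 0.19), Spic by 5.15 (SE 0.29), Esrrb by 3.42 (SE 0.17) and Tbx3 by 3.12 (SE 0.14). Lefty1 rose by 4.60 (SE 0.13) and Igf2 by 3.73 (SE 0.12). Plk2, higher in EpiLC in ethanol by 0.86 (SE 0.18), had a log2 difference of 0.12 (adjusted p = 0.608) in tamoxifen.

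The lists called between EpiLC and ESC in ethanol were called in tamoxifen too, in the same direction. In tamoxifen 14 of 16 naive genes fell and 0 rose, and 15 fell adjusted over the list alone (camera adjusted p = 1.46e-07, and adjusted p = 0.0820 with an estimated correlation), and 15 of 16 formative genes rose (5.49e-10, and 0.0414 with an estimated correlation). Imprinted genes rose in 13 of 15 cases (6.49e-06, and adjusted p = 0.0775 with an estimated correlation) and forkhead genes in 10 of 12 (5.48e-04, and adjusted p = 0.102 with an estimated correlation). FGF-ERK response genes rose in 11 of 15 and fell in 1 (0.00145, and adjusted p = 0.122 with an estimated correlation) and two-cell-like genes rose in 9 of 10 and fell in 1 (0.00360, and adjusted p = 0.212 with an estimated correlation). Nodal and TGF-beta response genes rose in 7 of 10 and fell in 1 (0.00393, and adjusted p = 0.102 with an estimated correlation) and interferon response genes rose in 9 of 13 and fell in 3 (0.00935, and adjusted p = 0.189 with an estimated correlation). Trophoblast genes, with 10 of 17 higher and 4 lower (5 lower adjusted over the list alone), and hypoxia and glycolysis genes, with 10 of 18 higher and 1 lower, were called in tamoxifen with an adjusted p of 0.0497 each, and with an estimated correlation had an adjusted p = 0.331 and an adjusted p = 0.189. The trophoblast call was lost with the block (0.0754), on round 1 arrays (0.0592) and without EpiLC tamoxifen sample 1 (0.0501) or ESC tamoxifen sample 1 (0.0760). The hypoxia call was lost with the block (0.0586), on round 1 arrays (0.0617) and without EpiLC tamoxifen sample 1 (0.0729) or 3 (0.0523) or ESC tamoxifen sample 1 (0.0645) or 3 (0.0540). With fry, further lists passed in tamoxifen: neuroectoderm (1.93e-06, and 0.0411 with camera under scaling to equal medians), neural crest (2.21e-06), fibroblast and stroma (1.94e-05), sterol (3.32e-04), histone acetylation (0.00228), primitive endoderm (0.00501) and unfolded protein and amino acid stress (0.00501).

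The tamoxifen effects were set against the developmental change to ask whether the loss of Foxd3 moves genes along it. In ESC, 221 genes rose with tamoxifen and were higher in EpiLC than in ESC, where 157 would be shared by independent calls, and 140 fell and were lower in EpiLC, where 87.2 would be. In EpiLC the larger excesses lay in opposite directions: 182 genes rose with tamoxifen and were lower in EpiLC than in ESC, where 118 would be shared, and 133 fell and were higher in EpiLC, where 60.9 would be. Tbx3 and Klf5 rose with tamoxifen in EpiLC and are lower in EpiLC than in ESC, while Car14 fell and is higher in EpiLC. In the other combinations, 159 and 100 genes were shared in ESC, where 139 and 98.5 would be, and 165 and 30 in EpiLC, where 133 and 53.9 would be.

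Across genes, the tamoxifen effect and the developmental change correlated at r = 0.121 (rho = 0.110) in ESC and r = -0.176 (rho = -0.230) in EpiLC. The ethanol samples enter both changes, which by itself gives a correlation. Simulated noise with a shared control, with neither a tamoxifen effect nor a developmental change, gave r = 0.501 for ESC and -0.499 for EpiLC. The shared control alone fixes these values, so they are no reference for the observed r, which includes real changes between cell types. Those simulated effects are small, so the covariances are the fairer measure: 0.0382 against 0.0121 simulated in ESC, and -0.0521 against -0.0120 in EpiLC. The simulation takes all samples as independent, while same-numbered tamoxifen and ethanol samples correlate, so the covariance brought by shared ethanol samples would be smaller than simulated. The ethanol samples were not split between the comparisons, so part of the excess of shared genes may come from them. The single estimate of the spread per gene may add to that excess as well. When samples were left out in turn, r ran from 0.0794 (without ESC tamoxifen sample 1) to 0.166 in ESC and from -0.224 to -0.131 in EpiLC.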

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

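The tests of cells left in the ESC state, of tamoxifen acting apart from Foxd3, of the hybridization rounds behind the differences between cell types, of p53 targets on round 2 arrays and of splits that keep pairs together were chosen only after the result was seen. The other tests of this part were set beforehand.

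What drew attention is that the tamoxifen effect differed between EpiLC and ESC, by a test of the difference itself, for 244 genes. The differences, as the EpiLC effect minus the ESC effect on the log2 scale, were 2.28 for Pdzk1, 2.07 for Foxd4, 2.00 for Dnd1, 1.95 for Gbp2b, 1.80 for Edn1, 1.78 for Gbp2, 1.75 for Slc5a5 and 1.74 for Lefty1. They were 1.22 for Isg15, 1.20 for Slc47a1, 1.19 for Car4, 1.13 for Ascl2, 1.00 for Bahcc1, 0.98 for Igf2, 0.93 for Klf5, 0.90 for Lefty2, 0.88 for Vim, 0.84 for Tbx3 and 0.56 for Ccnd1. Negative differences were -0.80 for Fas, -1.08 for Car14, -1.08 for Ldb2, -1.25 for Tdpoz4, -1.31 for Avpr1a, -1.36 for Celf4, -1.46 for Pmaip1, -1.64 for Rgcc, -1.71 for Eef1a2, -1.74 for Id2, -1.84 for Fgfbp3 and -1.85 for Gata6. Foxd4, Gbp2b, Gbp2, Slc5a5, Isg15, Car4, Avpr1a, Celf4, Ldb2 and Car14 were detected on no ESC array, Id2, Eef1a2 and Ascl2 in no ESC ethanol sample, Fas in no ethanol sample, and Avpr1a and Ldb2 in no tamoxifen sample either, while Pdzk1 was detected on 1 of 3 EpiLC ethanol arrays. For these genes the difference is a fitted value that depends on the background, so its size is not known. Of these 31 genes, 22 kept the call whichever sample was left out, and 10 under every alternative. Among gene lists the difference passed for trophoblast (camera adjusted p = 6.33e-04), neural crest (0.00120), naive pluripotency (0.0196), two-cell-like (0.0196), p53 target (0.0196) and interferon response (0.0266). With an estimated correlation none of the 6 passed (adjusted p = 0.206, 0.0890, 0.389, 0.389, 0.206 and 0.389 in the same order).

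The differences between cell types bear on whether the tamoxifen effect depends on the cell type. EpiLC ethanol samples were hybridized in round 1 alone, so a shift between rounds is a technical explanation to weigh. On round 1 arrays alone, where no such shift can act, the 244 genes had a median difference of 0.943 (SD 0.352), turned to the direction called, against 0.923 on all arrays, and 244 of 244 kept their sign. This argues against the rounds as the whole source, although these arrays are part of the data that selected the genes, and on them 57 of the genes were called and the other 187 had a median of 0.880. That Foxd3 has different targets in each cell type is a biological explanation consistent with these values, and it stays untested, as does a different response to tamoxifen itself.

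In ESC, the list of p53 targets rose with tamoxifen, though not every member did. On the arrays of round 2 alone, which hold all 6 ESC samples, the list kept an adjusted p of 2.35e-06, within a range of 1.60e-07 to 0.0112 over its alternatives, which argues against the hybridization rounds. Tamoxifen, or the recombinase it sets free, may raise p53 targets by damaging DNA apart from any loss of Foxd3. The design holds 0 tamoxifen samples with Foxd3 intact, so this and the loss of Foxd3 cannot be told apart. The same limit holds for every tamoxifen effect in the text.

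In EpiLC, naive pluripotency genes rose with tamoxifen. On round 1 arrays alone, which hold all 6 EpiLC samples, the list had an adjusted p of 0.00336, within a range of 1.38e-04 to 0.239 over its alternatives, the highest with an estimated correlation, which argues against the hybridization rounds. ESC-state cells left among the tamoxifen samples would also bring such transcripts, at a share of 5.05% for Klf2, 6.70% for Tbx3, 12.3% for Fbxo15 and 29.8% for Klf5. At the median share of 9.50%, 32 other abundant ESC transcripts at least 16-fold lower in EpiLC would rise by a median of 1.57, and at the lowest share by 1.03, against 0.134 observed (SD 0.297), and 0 of 32 rose as far at either share, which argues against unchanged ESC as the whole source. Among 132 other ESC-enriched genes detected on every EpiLC array the median rise was 0.276 (SD 0.362), short of the 0.585 needed by less than the spread, so a smaller share or cells between the 2 states stay open, as does a change within the cells, and the labels name no sort.

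For the counts of called genes, the samples were split in every other way. For ESC the real split called 856 genes and the highest other 1, for EpiLC 651 and 8, for EpiLC against ESC in ethanol 5300 and 0, and in tamoxifen 5326 and 0. In each comparison 1 of 10 splits gave as many genes, the real one, and 10 splits are too few for a share under 0.05. In every other split the real difference lies within the groups and widens their spread, which by itself lowers the count. The counts of the other splits are therefore no measure of what chance gives. Of the 10 splits, 4 part every same-numbered pair, the real one included, and the other 3 of these called 0 genes in each comparison. For the difference between the effects, 1 of 100 drawn splits gave as many genes, the real one with 244, and the highest other gave 0. These splits exchange single samples between the cell types within a treatment, after the mean of each cell type was removed. A real difference between the effects then lies within the mixed groups and widens their spread, so the 0 is no measure of what chance gives. Among them, 4 of the 100 keep every same-numbered tamoxifen and ethanol pair together. Of the 10 splits that do so, 1 gave as many genes, the real one with 244, and the highest other gave 0. These splits mix the effects in the same way, so their 0 is no measure of chance either, and 10 are too few for a share under 0.05.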

How the results depend on the processing

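Leaving out sample number 1 from both groups, round 2 arrays alone for lists and leaving out samples for lists were chosen after seeing the data, and all other alternatives beforehand. No called gene or list among those named turned its direction, but the balance of counts did. More genes were lower than higher for the difference under scaling to equal medians (78 higher, 258 lower), with the block (555 and 592) and with plain means of arrays (94 and 98), and for cell types in tamoxifen under scaling to equal medians (2096 and 3007). Foxd3 stayed uncalled under all 20 alternatives in ESC and 19 in EpiLC, with a change of 0.01 in ESC without ethanol sample 3. The ESC count of 856 stayed within 1.5 times under 15 of 25 alternatives, the EpiLC count of 651 under 14 of 24, the difference count of 244 under 17 of 28 and the shared count of 168 under 14 of 22. Counts between cell types stayed so under 22 of 23 in ethanol and in tamoxifen. With the sample number as a replicate block, counts were 2039 (ESC), 1876 (EpiLC), 1147 (difference) and 583 (shared). On round 1 arrays they were 390, 336, 61 and 63, and with the authors' normalized values 1064 (EpiLC), 397 (difference) and 267 (shared). Requiring at least a 1.5-fold change gave 486 (ESC), 364 (EpiLC), 3434 (EpiLC against ESC in ethanol) and 3368 (in tamoxifen), and an adjusted p under 0.01 gave 362, 236 and, for the difference, 40, as a stricter threshold must lower a count. Array weights gave 1448 in ESC, a fit of the 2 groups alone 212 in EpiLC, and leaving number 1 out of both groups 300 in ESC and 275 in EpiLC, where fewer samples remain. Leaving out single samples gave 523 to 579 (ESC), 357 to 548 (EpiLC), 109 to 198 (difference), 104 to 156 (shared), 4732 to 5016 (cell types in ethanol) and 4709 to 5138 (in tamoxifen). The correlation of the tamoxifen effect with the developmental change was 0.176 in ESC on round 1 arrays and -0.140 in EpiLC in the authors' table, and without single samples 0.0794 to 0.166 and -0.224 to -0.131. It was judged against the SD between sample numbers, 0.0512 and 0.0234, a spread chosen after the values were seen in place of the much smaller SD of the simulation, 0.00997 and 0.0106, against which most alternatives differ. Other than where stated, the cause was not tested.

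Of the named genes called, 33 of 59 kept their call in ESC under every alternative, 25 of 54 in EpiLC, 71 of 75 between cell types in ethanol, 70 of 74 in tamoxifen and 10 of 31 for the difference. When single samples were left out, 42, 37, 73, 73 and 22 kept it. In ethanol the sample numbers are not taken as pairs of ESC and EpiLC (correlations 0.0599, 0.121 and 0.253, though every sample correlated best with its own number). For named genes in the tamoxifen effects, the block added Cdx1, Twist1 and Foxa3 in ESC and Sall4, Gsc, Gbx2, Eef1a2 and Rgcc in EpiLC, and 26 genes for the difference. It changed no other call of a named gene or list than these and those given beside the results. Genes near background limit the text: Foxd3 was never detected, folds against a group with no detected array are bounds, and the size of a change from a group detected on few arrays depends on the background.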

Other observations

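Lists without a camera call also held genes that differed between EpiLC and ESC in ethanol. Of all 9422 genes tested, 56.3% were called in this comparison. A list count near that share says nothing particular about the list. Among 17 trophoblast genes 9 were higher and 6 lower (camera adjusted p = 0.317), with the keratin Krt18 higher by 3.41 (SE 0.19, n = 3 per group) and the transcription factor Tead4 lower by -2.86 (SE 0.13). Among 8 neural crest genes 3 were higher and 3 lower (adjusted p = 0.728): Msx1 was at least 11.6-fold higher and the receptor Ngfr lower by -3.21 (SE 0.11). Among 18 hypoxia and glycolysis genes 10 were higher and 2 lower (10 and 3 over the list alone, adjusted p = 0.154), with Egln3, an oxygen-sensing hydroxylase, higher by a fitted 2.45 (SE 0.20, detected on 1 of 5 ESC arrays) and the glycolytic enzyme Pfkp lower by -2.99 (SE 0.17). Among 18 p53 targets 7 were higher and 5 lower (8 and 5 over the list alone, adjusted p = 0.635), with Pmaip1 higher by 2.69 (SE 0.17). The Wnt feedback inhibitor Notum was at least 17.9-fold lower, in a list with 4 of 10 genes higher and 2 lower (adjusted p = 0.935).

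The remaining lists without a call held such genes too. Among 16 shared pluripotency genes 4 were higher and 4 lower (adjusted p = 0.652), with Lin28a higher by 1.77 (SE 0.33) and Mybl2 lower by -1.71 (SE 0.09). Among 12 germline genes 3 were higher and 6 lower (adjusted p = 0.504), with Nanos3 at least 5.12-fold lower. Among 12 primitive endoderm genes 5 were higher and 4 lower (6 and 4 over the list alone, adjusted p = 0.476), with Fst higher by 2.70 (SE 0.15). Among 19 histone acetylation and Brg1 complex genes 5 were higher and 2 lower (adjusted p = 0.652), with the acetyltransferase Ep300 higher by 0.66 (SE 0.11) and Kat2b lower by -1.29 (SE 0.26). Among 18 genes of unfolded protein and amino acid stress 9 were higher and 4 lower (10 and 4 over the list alone, adjusted p = 0.476), with Cebpb higher by 1.73 (SE 0.15) and Nupr1 lower by -2.61 (SE 0.28). Among 11 mesoderm and definitive endoderm genes 3 were higher and 5 lower (4 and 5 over the list alone, adjusted p = 0.643), among 5 neuroectoderm genes 4 and 1 (adjusted p = 0.197), and among 14 cell cycle genes 4 and 3 (adjusted p = 0.728).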
